A study of Mus musculus with 4 samples.

How the data were processed

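Gene expression was measured in primary keratinocytes from newborn C57BL/6 mice, labelled WT or p38a-KO, without irradiation and 4 h after UVB at 75 mJ/cm2. There is 1 array for each of the 4 groups, and groups were taken from the genotype and stress labels. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns and labelled with biotin by a 3' in vitro transcription kit from 0.2 ug RNA. Per the submitters' processing notes, the arrays were summarised with MAS5, and the deposited values are signal intensity per probe set on a linear scale. The MAS5 version, the scaling target and detection calls are not given in the sources used here. The 2% trimmed mean signal was 178.3 in unirradiated WT, 113.1 in irradiated WT, 199.5 in unirradiated KO-labelled and 117.1 in irradiated KO-labelled cells, so the arrays were not scaled to a common trimmed mean over all probe sets.

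The table holds 45101 probe sets, of which 64 are controls, 34945 map to exactly 1 gene symbol, 932 map to several and 9160 carry no symbol. Names come from the platform annotation, checked against a RefSeq gene table of the mouse assembly, in which 34741 of the 34945 probe sets were found by gene ID with 0 symbols changed. Probe sets with several symbols or none were not used for genes, which left 18193 genes. Each gene was represented by its probe set with the highest mean signal. The floor was the median over probe sets of the mean signal of the 4 arrays, 24.9 units, and lower values were raised to it. Signal reached the floor for 54.4% of probe sets in unirradiated WT, 43.1% in irradiated WT, 57.9% in unirradiated KO-labelled and 43.6% in irradiated KO-labelled cells. Genes count as changed at 2-fold or more, and a fold against a value below the floor is given as at least that fold.

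The comparisons were UVB against no irradiation in each genotype, KO-labelled against WT in each condition, and the difference of the 2 UVB responses. Pairwise comparisons have no test, since each group has 1 array. An additive model of irradiation and genotype was fitted with limma on log2 signal of the 11379 genes with mean signal at or above the floor, with empirical Bayes moderation, an intensity trend, 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. The fit was tested on simulated data with 11379 genes, in which it recovered 46 of 100 genes with a true log2 change of 1 and 92 of 100 with a change of 2, with 2 false calls. The simulation changed 200 genes by irradiation only, far fewer than the 80 and 7899 that passed in the data. Its noise was independent, with no floor and no differences between cultures. It therefore does not give the error rate of the calls below, and the genotype effect was not simulated.

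In total 36 gene lists with 715 entries were fixed, and 643 entries matched a gene on the array. They cover p38 pathway kinases, MAPK phosphatases, immediate early genes, p53 targets, nucleotide excision repair, apoptosis, inflammatory cytokines, chemokines, NF-kB feedback, AU-rich-element and decay factors, EGFR ligands and receptors, prostaglandins, interferon-stimulated genes, the unfolded protein response, heat shock, NRF2, basal, suprabasal and late differentiation, wound keratins and alarmins, lipid barrier, S phase, G2 and M phase, Notch and Wnt, TGF-beta, the circadian clock, ribosomal proteins, histones and reference genes. Markers of fibroblasts, melanocytes, leukocytes, endothelium, muscle, Merkel, sweat or hair follicle cells and erythroid cells complete them. The median of each list was set against 10000 random lists matched in 20 bins of mean signal, and a list counts as outside them below percentile 2.5 or above 97.5. List members were also counted by limma result, over all genes and adjusted over the list alone.

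Named genes follow a fixed rule. For each comparison these are the 10 largest differences in each direction of at least 2-fold with all its arrays at or above the floor and agreeing probe sets, the 5 largest bounds in each direction, the 10 largest passing limma effects in each direction, the 3 largest members of each list, and Mapk14. Gene-model names, Y-linked genes and Xist are not named. The groups, comparisons, lists, naming rule, main settings and the first 10 alternatives were chosen before the data were examined.

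The alternatives were quantile normalization, median centring of the arrays, floors at the 25th and 75th percentile (9.38 and 128.9 units), thresholds of 1.5-fold and 3-fold, the mean over a gene's probe sets, leaving out probe sets marked as cross-hybridising, limma without the intensity trend, and limma with only the tested factor. Centring scaled each array by its median over all non-control probe sets with mean signal at or above the floor, not over the genes. After it, genes at or above the floor had a median UVB response of 0.32 in WT and 0.28 in KO-labelled cells. Counts of genes rising after UVB under centring include this offset. Random lists matched on both signal and gene span were added after the data were seen. Gene spans come from the RefSeq table, and 13 of the 11379 genes had none. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw image files were not used here.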

Results

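Primary keratinocytes, the epithelial cells that build the epidermis, were cultured from newborn C57BL/6 mice that were wild type (WT) or labelled as knockout (KO) for p38alpha, a stress-activated MAP kinase encoded by Mapk14. RNA was measured on 4 Affymetrix expression arrays, 1 from unirradiated cells and 1 from cells 4 h after ultraviolet B (UVB) irradiation at 75 mJ/cm2 for each genotype. Each group therefore has 1 array, no pairwise difference has a replicate check, and the number of arrays limits the precision of every value. The design asks how the cells respond to UVB, how the genotypes differ, and whether the response differs between them. The sample titles name no mock-treated control at 4 h. Each UVB response therefore also holds any effect of 4 h in culture and of handling. The median MAS5 signal over the array was 30.3 units in unirradiated WT cells, 18.7 in irradiated WT cells, 34.5 in unirradiated KO-labelled cells and 18.7 in irradiated KO-labelled cells. A floor of 24.9 units was used throughout, and 11379 of 18193 named genes had a mean signal at or above it.

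Mapk14, the targeted gene, was not lower in the KO-labelled cells by its brightest probe set, which read 985.4 units in unirradiated WT cells, 292.5 in irradiated WT cells, 1449 in unirradiated KO-labelled cells and 646.8 in irradiated KO-labelled cells. Of the 6 Mapk14 probe sets, 5 had a mean signal at or above the floor, and 1 of these, a dim one, was lower in unirradiated KO-labelled cells, at 37.7 units against 51.3. Expression arrays of this kind read the 3' end of a transcript, and the sources used here do not give the deleted part of the gene, so a probe set outside that part cannot check the genotype. The samples are called KO-labelled for that reason, and every genotype direction below rests on the labels.

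Signal 4 h after UVB was lower for most genes in both genotypes. The median log2 difference of the 11379 genes was -0.70 in WT and -0.82 in KO-labelled cells, while the 18 hybridisation spike-in probe sets, RNAs added to every array at that step, had medians of 0.01 and 0.12. The shift depended on signal level. It was -0.96 in WT and -1.03 in KO-labelled cells for the 4250 genes between 100 and 400 units, and -0.09 and -0.02 for the 123 genes above 6400 units, where a ceiling of the scanner range cannot be excluded. The 2 medians were 0.05 and 0.06 over 11418 genes after quantile normalization, and 0.32 and 0.28 over 11431 genes after median centring. Gene groups are therefore described relative to random gene lists matched on mean signal, with the list's percentile among 10000 such lists as a description of these arrays.

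**Figure D1:**
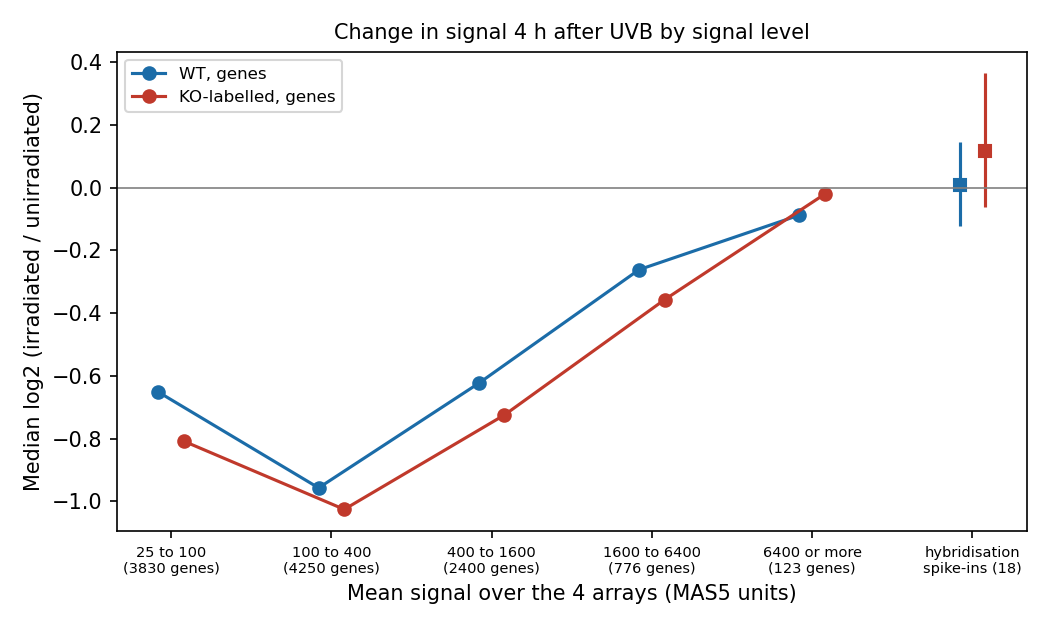
Median log2 ratio of irradiated over unirradiated signal (vertical axis) for genes grouped by mean MAS5 signal (horizontal axis), in WT (blue) and KO-labelled cells (red); squares are the medians of 18 hybridisation spike-in probe sets and their lines run from the lowest to the highest. Genes between 100 and 400 units lie at -0.96 and -1.03, and the spike-ins at 0.01 and 0.12.

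The genes with the highest ratio after UVB in WT cells included late cornified envelope genes, a growth factor and a chemokine. Lce3c, a late cornified envelope gene, was 11.7-fold higher, and Lce3f, Sprr2f, Lce1i and Lce1f of the same epidermal differentiation group were 6.65-fold, 5.20-fold, 3.91-fold and 3.56-fold higher. Hbegf, a ligand of the EGF receptor, was 5.68-fold higher, and Nppb, which encodes a natriuretic peptide, 7.16-fold higher. Cxcl2, a neutrophil chemokine, was 3.89-fold higher, Zfp36, which encodes a protein that promotes decay of cytokine mRNAs, 3.68-fold higher, and the stress gene Ddit4l 3.57-fold higher. Tnf was at least 3.85-fold higher, Nkx2-9 at least 4.84-fold, Adamtsl4 at least 2.42-fold, Ccno at least 2.36-fold and Csf2, a cytokine, at least 2.30-fold, each against an unirradiated value below the floor.

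The largest falls in WT were far below the array-wide shift. Iffo2 was 23.4-fold lower, Zbtb44 15.8-fold, Sgms1, a sphingomyelin synthase, 15.8-fold, and Lgr4, an R-spondin receptor, 14.6-fold. Pum2, an RNA-binding repressor, was 13.8-fold lower, Stox2 13.7-fold, the kinase Tlk1 12.8-fold, Rnf145 12.8-fold, Tmem51 12.7-fold and the Wnt co-receptor Lrp6 12.7-fold. Gas1 was at least 23.2-fold lower, Rapgef2 at least 18.3-fold, Nlk at least 16.7-fold, Vav3 at least 12.8-fold and Mosmo at least 11.9-fold. As deposited, 68 genes were at least 2-fold higher and 3962 at least 2-fold lower in WT. Quantile normalization gave 622 and 1086, and median centring gave 1309 and 843, so the split between higher and lower genes depends on the scaling. Folds of single genes, here and below, are as deposited and depend on the scaling too. In WT the median log2 difference was -0.70 as deposited, 0.05 with quantile normalization and 0.32 with centring.

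In KO-labelled cells, only 21 genes were at least 2-fold higher after UVB and 4492 at least 2-fold lower. Quantile normalization gave 484 and 934, and median centring gave 1022 and 740. Fos, a member of the AP-1 transcription factor, was 3.32-fold higher, Ddit4l 2.64-fold, Rem2 2.63-fold, the mitochondrial gene ND5 2.31-fold, the growth arrest gene Gadd45a 2.29-fold, Hbegf 2.11-fold and Gstm3 2.11-fold. Against an unirradiated value below the floor, H3f3b, a histone H3.3 gene, was at least 4.19-fold higher, Lce3c at least 3.24-fold, Rbp2 at least 2.58-fold, Lce3f at least 2.57-fold and Smim27 at least 2.22-fold. Iffo2 was 18.3-fold lower, Wasl, an activator of actin nucleation, 16.8-fold, Sgms1 16.7-fold, Tgs1 15.1-fold, Auts2 14.9-fold, Tsc22d2 14.3-fold, Eva1a 13.9-fold, Rnf145 13.7-fold, Fnip1 13.4-fold and the polymerase III factor Bdp1 13.2-fold. Rapgef2 was at least 21.5-fold lower, Dcp1a, a decapping factor, at least 13.3-fold, Irs1 at least 12.7-fold, Casp8ap2 at least 12.5-fold and Mosmo at least 11.6-fold.

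Several of these genes also passed a test over both genotypes. Hbegf rose by 1.79 on the log2 scale (SE 0.26, limma adjusted p = 0.000245). Lce3c rose by at least 2.62 (limma adjusted p = 0.000182) and Lce3f by at least 2.05 (limma adjusted p = 0.000308), since 1 unirradiated value of each was raised to the floor. Fos rose by 1.70, Ddit4l by 1.62 and Tsc22d1, a leucine zipper regulator, by 1.56, and each was higher in both genotypes. Iffo2 fell by 4.37 on the log2 scale (SE 0.13, limma adjusted p = 1.0e-06), Sgms1 fell by 4.02 and Rnf145 fell by 3.73, while Rapgef2 fell by at least 4.31 and Gas1 by at least 4.06, with irradiated values raised to the floor. In limma's additive model of irradiation and genotype, with 1 residual degree of freedom, 80 genes rose and 7899 fell of 11379 tested. The residual is the disagreement between the 2 genotypes' responses. Moderation combined it with a prior from the intensity trend over all genes, with 8.13 degrees of freedom against 1 for the gene itself. These p-values therefore measure that disagreement, mostly as pooled over genes of similar signal, and not a spread between cultures. The same model found 2314 higher and 2302 lower genes after quantile normalization, and 4184 and 1702 after median centring.

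Responses of single genes were correlated between the genotypes. Across the 11379 genes, which are not independent replicates, the responses had a Pearson correlation of 0.81 and a Spearman correlation of 0.78, and the 2 responses share no array. Of the genes at least 2-fold higher, 10 were shared by both genotypes against 0.110 for independent lists over the 11379 genes, and of those at least 2-fold lower, 3293 were shared against 1556. Quantile normalization gave 178 against 25.7 higher and 674 against 88.7 lower, and median centring gave 506 against 114.7 and 508 against 54.4. Adamtsl4 was the 1 gene past 2-fold in opposite directions as deposited, and there were 4 with quantile normalization and 2 with centring. The Pearson correlation was 0.61 with the floor at the 25th percentile of signal.

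**Figure D2:**
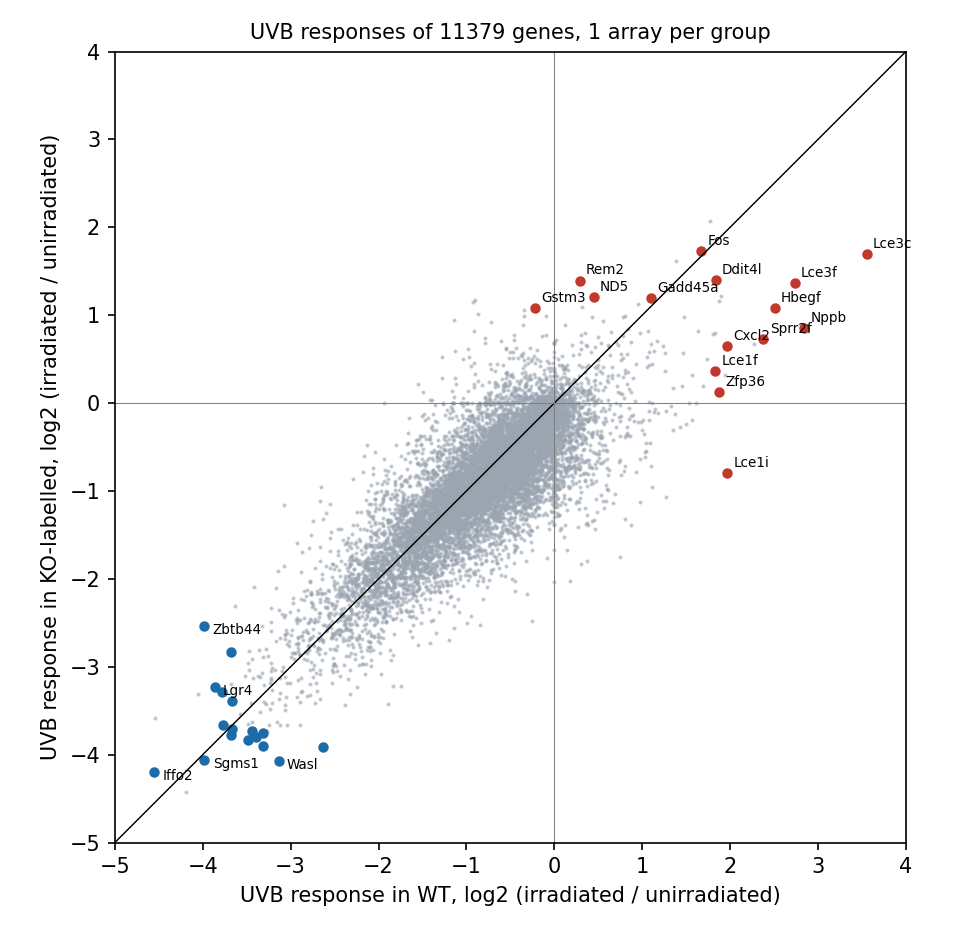
Log2 ratio of irradiated over unirradiated signal in WT (horizontal axis) and in KO-labelled cells (vertical axis) for 11379 genes, each a grey point from 1 array per group; the diagonal marks equal responses, and red and blue points are the named genes higher and lower after UVB. The correlation across genes is 0.81, and Lce1i, Zfp36, Nppb and Lce3c lie below the diagonal. For Lce3c the KO-labelled response is a lower bound, since its unirradiated value was raised to the floor.

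Early response, inflammatory and late differentiation groups stood above lists matched on signal after UVB in both genotypes. Before matching, medians for immediate early genes, chemokines, inflammatory cytokines and late differentiation were -0.39, -0.24, -0.39 and -0.30 in KO-labelled cells. There 18 of 23, 11 of 13, 13 of 18 and 16 of 24 members lay below 0, so as deposited these lists fell less than matched lists. In WT the 4 medians were 0.27, 0.09, -0.19 and 0.02. Against lists matched also on gene span, which were added after the data were seen, the KO-labelled immediate early and late differentiation lists lay at percentiles 83.3 and 96.42, inside the bounds. Markers of other cell types also lay above matched lists, with fibroblast markers at 0.33 (percentile 97.7) and melanocyte markers at 0.39 (percentile 97.74) in WT. With median centring these WT lists lay inside the bounds (percentiles 91.31 and 74.67), and with quantile normalization the melanocyte list did (percentile 76.17). In KO-labelled cells leukocyte markers lay at 0.69 (percentile 99.52) and muscle markers at 0.60 (percentile 98.53), with 6 measured members in each list. Before matching, the leukocyte median there was 0, with 2 members above 0 and 2 below, against -0.69 for matched lists. The muscle median was -0.20, with 1 member above 0 and 5 below. A difference of 0 can come from values raised to the floor, which cannot fall. Immediate early and AP-1 genes lay 0.89 above matched lists in WT (percentile 100) and 0.34 above in KO-labelled cells (percentile 99.65), and 4 of 23 rose and 9 fell in the limma fit. Fos rose, whereas Fosl2 and Myc were 9.42-fold and 5.93-fold lower in WT and fell in the limma fit. Chemokines lay 0.80 and 0.59 above matched lists (percentiles 100 and 99.96), with 3 of 13 members rising and 2 falling. Cxcl2, Ccl20 and Cxcl1 rose, by 3.89-fold, 2.73-fold and 2.16-fold in WT. Inflammatory cytokines lay 0.58 and 0.49 above (percentiles 99.98 and 99.89), and 1 of 18 rose and 6 fell, against 9 of 19 rising and 0 falling with quantile normalization. Tnf rose, and Csf1, a macrophage growth factor, was 5.04-fold lower in WT and 7.35-fold lower in KO-labelled cells. Late differentiation and cornified envelope genes lay 0.64 and 0.45 above (percentiles 100 and 99.98), and 6 of 24 rose and 7 fell; the KO-labelled list lay at 0.24 with quantile normalization and 0.27 with centring, where its percentile was 97.46. Adjusted over the list alone, 4 immediate early genes rose and 9 fell, 1 inflammatory cytokine rose and 5 fell, 1 chemokine rose and 2 fell, and 6 late differentiation genes rose and 6 fell. With quantile normalization, 13 of 23 immediate early genes rose and 5 fell, 8 of 15 chemokines rose and 0 fell, and 13 of 24 late differentiation genes rose and 0 fell.

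Receptor, signalling and lipid groups stood below lists matched on signal after UVB. Against lists matched also on gene span, the lipid barrier list lay at percentiles 2.70 and 3.18 and the EGFR list in WT at 3.04, inside the bounds. Notch and Wnt signalling genes lay -0.67 relative to matched lists in WT (percentile 0.07) and -0.45 in KO-labelled cells (percentile 1.18), and 15 of 17 fell. The Notch ligand Dll1 was 5.91-fold lower in WT and 5.44-fold lower in KO-labelled cells, and Notch2 and Jag1 were 4.39-fold and 4.03-fold lower in WT. TGF-beta and SMAD genes lay at -0.49 and -0.69 (percentiles 1.01 and 0.03), and 13 of 17 fell, with the receptor Tgfbr2 6.71-fold and 5.95-fold lower. Among EGFR ligands and receptors, the list lay at -0.60 in WT (percentile 1.93) and -0.41 in KO-labelled cells (percentile 5.82, and 0.41 with quantile normalization). Here 8 of 11 fell, with Erbb2 7.86-fold and Egfr 6.83-fold lower in WT, and 2 rose, Hbegf and Ereg. Lipid barrier genes lay at -0.35 in both genotypes (percentiles 1.54 and 1.45) and 18 of 19 fell, with Sqle and Hmgcs1 of sterol synthesis 4.97-fold and 4.61-fold lower in WT. Adjusted over the list alone, 15 Notch and Wnt, 14 TGF-beta, 8 EGFR and 18 lipid barrier genes fell. With median centring, 5 of 17 Notch and Wnt genes, 8 of 16 TGF-beta genes, 5 of 11 EGFR genes and 6 of 19 lipid barrier genes fell, and 4, 2, 3 and 7 rose.

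Unirradiated KO-labelled cells had lower signal of cornified envelope and alarmin genes than unirradiated WT cells, and higher signal of fibroblast markers, while lipid barrier genes lay at -0.06 relative to matched lists (percentile 13.93). Mal was 4.90-fold lower, the glutamate transporter gene Slc1a1 4.06-fold, the protease inhibitor gene Spink5 3.98-fold, the keratin gene Krt23 3.52-fold and Crct1 of the epidermal differentiation region 3.49-fold. S100a9, an alarmin, was 3.32-fold lower, Homer2 3.32-fold, Lce1a1 3.23-fold, Cnfn, which encodes cornifelin of the cornified envelope, 3.04-fold and the IL-36 cytokine gene Il1f6 3.02-fold. Oas1a was at least 5.68-fold lower, the collagenase gene Mmp13 at least 3.88-fold, Lce3c at least 3.15-fold, Plxnb3 at least 3.15-fold and Samd10 at least 2.92-fold. Kit was 3.64-fold higher, Tagln, an actin-binding gene of smooth muscle and fibroblasts, 3.63-fold, Pcolce, a procollagen processing gene, 3.56-fold, Wfdc2 3.21-fold, Dpysl3 3.13-fold and Fgf13 3.09-fold. Igfbp6 was 2.87-fold higher, Map2k6, which encodes a kinase that activates p38, 2.82-fold, Mgst3 2.81-fold and Sgsm2 2.77-fold. Art1 was at least 4.13-fold higher, Depp1 at least 4.11-fold, Galnt16 at least 3.75-fold, Glrb at least 3.43-fold and Nkx2-9 at least 3.28-fold.

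Among the groups in unirradiated cells, late differentiation genes lay at -0.65 relative to matched lists, with 4 of 24 at least 2-fold lower and Sprr2f 2.71-fold higher. Wound and stress keratins and alarmins lay at -0.53, with 6 of 17 at least 2-fold lower, and both medians were at percentile 0. S100a8 was 2.94-fold lower. NRF2 and oxidative stress genes lay at -0.24 (percentile 0.03) and at -0.15 with quantile normalization, with Gsta4 2.5-fold and Hmox1 2.07-fold lower. MAPK phosphatases lay at -0.20 (percentile 1.29), immediate early genes at -0.15 (percentile 0.32) and ribosomal proteins at -0.11 (percentile 0.55), the last at 0.013 (percentile 63.98) with quantile normalization. G2 and M phase genes lay at 0.11 (percentile 99.46), with 25 of 27 above 0, and basal keratinocyte genes at -0.01 (percentile 46.39). The median of all 11379 genes was itself above 0, at 0.16. In the limma fit for genotype over both conditions, 0 of 27 G2 and M phase genes passed, or 2 as higher adjusted over the list alone. Beside these groups, fibroblast markers lay 0.71 above matched lists (percentile 100), with Thy1 2.44-fold, Col1a2 2.30-fold and Col6a2 2.29-fold higher, and melanocyte markers 0.38 above (percentile 99.99), whereas leukocyte and Langerhans markers lay at -0.43 (percentile 1.78), but at -0.24 (percentile 3.0) with median centring, and endothelial markers at -0.53 (percentile 1.43). The leukocyte and endothelial lists have only 6 and 4 measured members, with 0 past 2-fold in either. As deposited, 203 genes were at least 2-fold higher and 87 at least 2-fold lower in KO-labelled cells. Quantile normalization gave 60 and 83, and median centring gave 59 and 76. The median log2 difference was 0.16 over 11379 genes as deposited and 0 over the 11418 and 11431 genes at or above the floor after these scalings.

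After UVB the genotypes differed more in cornified envelope and alarmin genes, and lipid barrier genes lay at -0.03 (percentile 32.25). Lce3c was 11.4-fold lower in irradiated KO-labelled cells than in irradiated WT cells, Slc1a1 8.45-fold, Lce1i 8.27-fold, the beta-defensin gene Defb3 7.36-fold, Lce3f 6.96-fold and Cnfn 6.18-fold. Sprr2i was 5.86-fold lower, Prdm1, a transcriptional repressor, 5.76-fold, Lcn2, an iron-scavenging antibacterial protein, 5.67-fold and Mal 5.39-fold. The chemokine gene Cxcl3 was at least 11.8-fold lower, the beta-defensin gene Defb4 at least 3.89-fold, Cdk5r1 at least 3.77-fold, Mmp13 at least 3.68-fold and Bcl3, an NF-kB cofactor, at least 3.42-fold. Map2k6 was 4.69-fold higher, Igfbp6 4.11-fold, Fhit 3.55-fold, Mgst3 3.53-fold, Slc39a13 3.49-fold, the growth factor gene Ptn 3.35-fold, the DNA damage sensor gene Xpc 3.27-fold, Tgfbi 3.05-fold, Cdca7 2.83-fold and Ntn4 2.83-fold. Gas1 was at least 3.75-fold higher, Pik3r1 at least 3.39-fold, Mtif3 at least 3.36-fold, Fat2 at least 3.15-fold and Slc45a1 at least 3.06-fold.

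Wound and stress keratins and alarmins lay at -1.35 relative to matched lists in irradiated cells, with 9 of 17 at least 2-fold lower, and late differentiation genes at -1.09, with 13 of 24 at least 2-fold lower. MAPK phosphatases lay at -0.60, with Dusp1, the phosphatase that inactivates p38 and JNK, 2.63-fold and Dusp5 2.11-fold lower. Immediate early genes lay at -0.59, with Ier3 2.5-fold lower, and all 4 of these medians were at percentile 0. Prostaglandin pathway genes lay at -0.49 (percentile 0.07), with the cyclooxygenase gene Ptgs2 2.75-fold lower, and chemokines at -0.44 (percentile 0.01), with Cxcl2 4.38-fold and Ccl20 3.29-fold lower. Heat shock genes lay at -0.33 (percentile 0), with Cryab 2.77-fold lower, inflammatory cytokines at -0.30 (percentile 0.05) and at -0.48 with quantile normalization, with Il1f6 3.38-fold and Il1a 2.76-fold lower, and NF-kB feedback genes at -0.27 (percentile 0.25). NRF2 genes lay at -0.35 (percentile 0.01), p53 targets at -0.18 (percentile 0.06) and EGFR ligands and receptors at -0.27 (percentile 0.98), the last at -0.68 with quantile normalization and -0.66 with centring. Suprabasal genes moved both ways, with Krt10 2.59-fold higher and Tgm1, which encodes the enzyme that cross-links the cornified envelope, 2.54-fold lower. Fibroblast markers again lay above matched lists, by 0.62 (percentile 100), and 0 of 19 passed 2-fold, while melanocyte markers lay 0.21 above (percentile 95.94). As deposited, 163 genes were at least 2-fold higher and 169 at least 2-fold lower. Quantile normalization gave 259 and 321, and median centring gave 213 and 365.

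**Figure D3:**
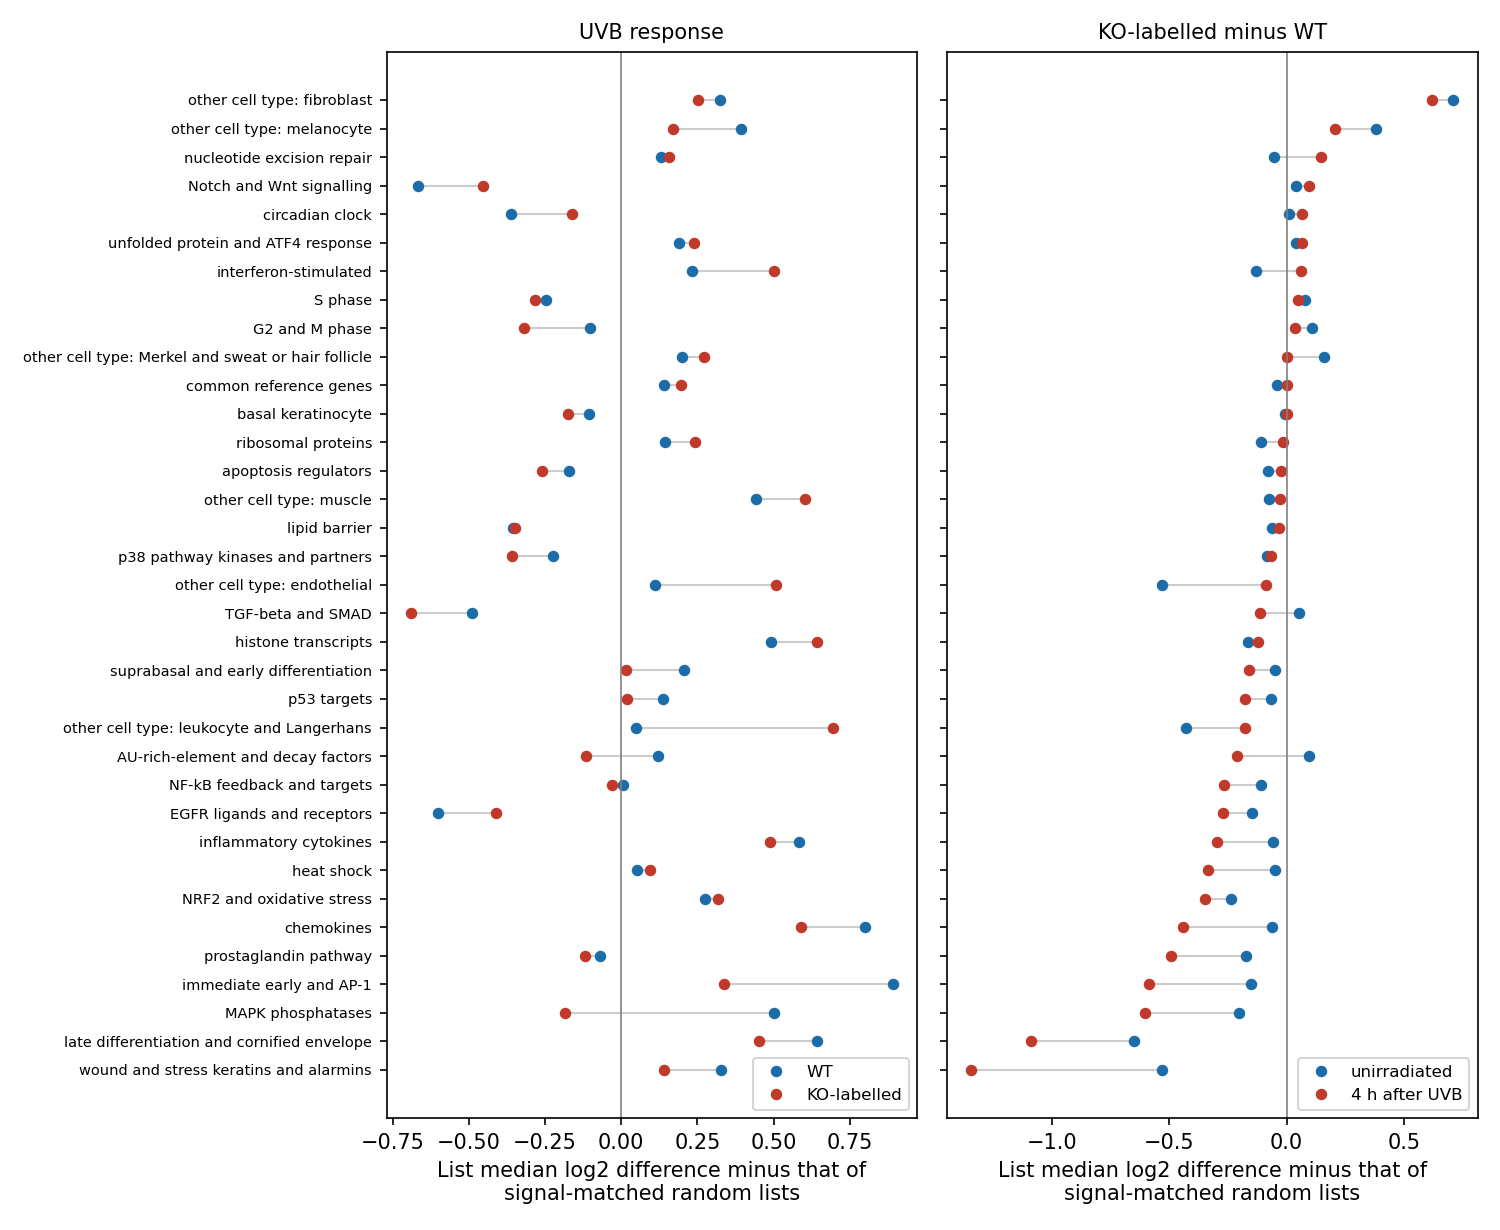
Median log2 difference of each gene list minus that of random lists matched on mean signal (horizontal axes), for the UVB response in WT (blue) and KO-labelled cells (red) on the left, and for KO-labelled minus WT in unirradiated (blue) and irradiated cells (red) on the right; grey lines join the 2 values of a list. On the right, wound and stress keratins and alarmins lie at -0.53 and -1.35, late differentiation genes at -0.65 and -1.09, and fibroblast markers at 0.71 and 0.62.

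Over both conditions, the limma fit gave 110 genes higher and 73 lower in KO-labelled cells, and these calls depend on the form of the test. Each genotype has 1 unirradiated and 1 irradiated array. The SEs and p-values therefore measure how far genotype differences agree between conditions, mostly as pooled over genes of similar signal, not a spread between cultures. The prior from all genes had 8.13 degrees of freedom against 1 for the gene itself, so the agreement of a single gene weighs little. Genotype also cannot be told apart from the animals the cells came from. Without the intensity trend of the variance it gave 0 and 0, with 1170 and 355 at an unadjusted p under 0.05, and with genotype as the only factor in the model it gave 0 and 0, with 17 and 31 at an unadjusted p under 0.05. Mal was lower by 2.36 on the log2 scale (SE 0.15), Spink5 by 2.13 (SE 0.13) and Crct1 by 2.09 (SE 0.14), each with a limma adjusted p of 0.000277. Slc1a1 was lower by 2.55 and Cnfn by 2.12, and Lce3c was lower by at least 2.59 and Cxcl3 by at least 2.31 (limma adjusted p = 0.0447), each with 1 KO-labelled value raised to the floor. Ptn was higher by 2.13 (SE 0.20, limma adjusted p = 0.00208), Map2k6 by 1.86, Igfbp6 by 1.78, Mgst3 by 1.66, Dpysl3 by 1.57, Tagln by 1.49, Capn6 by 1.45 and Pcolce by 1.45. Within the lists, 6 of 24 late differentiation genes and 6 of 17 alarmin genes passed as lower, and 10 of 19 fibroblast markers passed as higher. Adjusted over the list alone these counts were 17, 10 and 15. Genotype differences in the 2 conditions had a Pearson correlation of 0.35 across genes, 0.15 with the floor at the 25th percentile and 0.49 with the floor at the 75th. Of the genes at least 2-fold different, 24 higher genes were shared against 2.63 for independent lists over the 11379 genes, and 33 lower genes against 1.22.

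The named genes with a smaller UVB response in KO-labelled cells included Lce1i and Zfp36, and those with a larger one Txnip and Xpc. Lce1i was 3.91-fold higher after UVB in WT and 1.73-fold lower in KO-labelled cells, a 6.78-fold difference of responses. Zfp36 went from 487.3 to 1792 units in WT and from 475.3 to 518.9 in KO-labelled cells, a 3.37-fold difference. Nppb, the mitochondrial permeability gene Ppif, the vasoconstrictor gene Edn1, the connexin gene Gjb2 and Prdm1 had 3.96-fold, 3.53-fold, 3.41-fold, 3.40-fold and 3.70-fold smaller responses. Sgtb, Dennd6b, Scaf1 and Sprr2i completed the named genes, with 4.49-fold, 4.41-fold, 3.51-fold and 3.39-fold smaller responses. In the other direction, Txnip, an inhibitor of thioredoxin, had a 4.26-fold larger response, from 485.5 to 220.1 units in WT and from 263.2 to 508.6 in KO-labelled cells. Wbp2nl, Xpc, Sardh, Bloc1s5 and Rasl11a had 3.13-fold, 3.07-fold, 3.03-fold, 2.92-fold and 2.88-fold larger responses, and Gne, Map3k12, Zfp637 and Zfp385c 2.80-fold, 2.77-fold, 2.64-fold and 2.59-fold larger ones.

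By group, MAPK phosphatases had a difference of responses 0.66 below matched lists, with 3 of 11 members past 2-fold. Dusp8 had a 2.98-fold, Dusp2 a 2.23-fold and Dusp5 a 2.04-fold smaller response. Late differentiation genes lay at -0.56, with 8 of 24 past 2-fold, among them Lce1h with a 3.20-fold smaller response, and both medians were at percentile 0. These 8 include Lce3c and Lce3f, whose unirradiated KO-labelled values were raised to the floor. Their KO-labelled responses are lower bounds, so their true shortfalls are at most the size counted and may lie under 2-fold. Chemokines lay at -0.54 (percentile 0.01) and at -0.35 with median centring, where 15 members were measured, with 4 of 13 past 2-fold as deposited. Cxcl2 and Ccl20 had 2.48-fold and 2.38-fold smaller responses, and Cxcl3 one at least 5.67-fold smaller, since its irradiated KO-labelled value lay below the floor. Prostaglandin pathway genes lay at -0.39 (percentile 0.34), with Ptgs2 at a 2.24-fold smaller response, and with the floor at the 75th percentile the list lay at 0.03. AU-rich-element and decay factors lay at -0.33 (percentile 0.29), led by Zfp36, and heat shock genes at -0.29 (percentile 0.05), or -0.16 with quantile normalization. Alarmins lay at -0.33 (percentile 0.04), or -0.50 with quantile normalization and -0.52 with centring, with Defb3 at a 2.99-fold smaller response. Immediate early genes lay at -0.25 (percentile 0.06), with Fosl1 at 2.58-fold and Nr4a1 at 2.22-fold, and with the floor at the 25th percentile the list lay at 0.10. Il24 and Tnf of the inflammatory cytokines had 3.35-fold and at least 3.09-fold smaller responses, while the list lay at -0.10 (percentile 17.53). The p53 targets lay at -0.16 (percentile 0.51). Basal keratinocyte genes lay at 0.13 (percentile 97.65, and 95.8 with quantile normalization) and ribosomal proteins at 0.10 (percentile 97.8, and 20.46 with quantile normalization). Hbegf and Ereg, ligands of the EGF receptor, had 2.69-fold and 2.82-fold smaller responses, while their list lay at -0.13 (percentile 12.26) as deposited, -0.59 with quantile normalization and -0.55 with median centring, both at percentile 0. Fibroblast markers lay at -0.11 (percentile 11.72), but at -0.22 (percentile 0.68) with quantile normalization, and melanocyte markers at -0.19 (percentile 6.08).

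**Figure D4:**
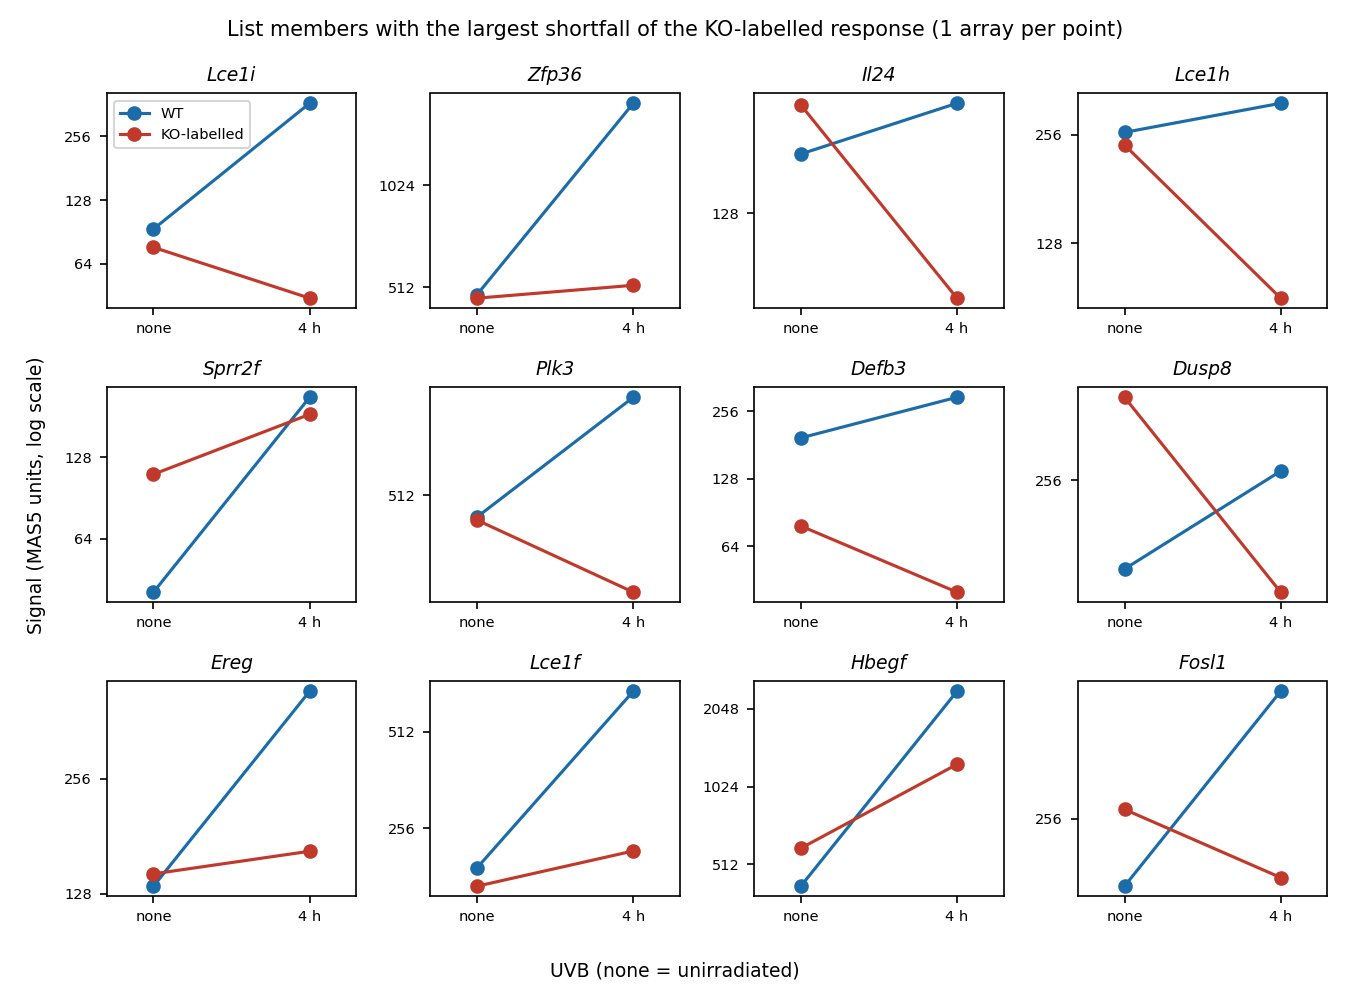
MAS5 signal (vertical axes, log scale, 1 array per point) without UVB and 4 h after UVB in WT (blue) and KO-labelled cells (red) for the 12 members of the fixed gene lists with the most negative difference of responses among those at or above the floor on all 4 arrays. Zfp36 runs from 487.3 to 1792 units in WT and from 475.3 to 518.9 in KO-labelled cells.

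As deposited, 159 genes had a response at least 2-fold larger in KO-labelled cells and 355 one at least 2-fold smaller, and the median difference of responses over the 11379 genes was -0.08. The irradiated KO-labelled array also had the highest signal of the 3 control probe sets of 18S rRNA, at 1232, 234.3 and 183.5 units against at most 127.7, 128.4 and 112.5 on the other arrays. In WT these sets were also brighter after UVB, at 127.7, 128.4 and 104.3 units against 70.9, 55.1 and 74.2 unirradiated. Quantile normalization gave 291 larger and 319 smaller responses, and median centring gave 237 and 353. With 1 array per group the difference of responses has no test. Probe sets of the same gene on the same arrays differed by a pooled SD of 0.42 on the log2 scale for this difference, over 5209 genes with at least 2 probe sets. This is a spread between probe sets within arrays and not a measure of technical error alone. It does not include differences between cultures.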

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

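Of the tests in this part, those of hybridisation, RNA degradation, keratinocyte share and culture state, and the restriction of the scaling tests to quantile normalization, were chosen only after the result was seen. Adamtsl4 responded to UVB in opposite directions in the 2 genotypes. Its signal went from 23.6 to 60.2 units in WT and from 55.0 to 26.2 in KO-labelled cells, a difference of responses of -2.34 or lower on the log2 scale, since the unirradiated WT value was raised to the floor. The difference was not tested. The control probe sets of 18S rRNA, which no comparison uses, were highest on the irradiated KO-labelled array. The 5' set read 1232 units there against 70.9, 127.7 and 83.9 on the others, the middle set 234.3 against 55.1, 128.4 and 76.0, and the 3' set 183.5 against 74.2, 104.3 and 112.5. In both genotypes all 3 sets were brighter on the irradiated array than on the unirradiated one. No explanation for these differences was tested, and every comparison with irradiated KO-labelled cells rests on the 1 array of that group.

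Most transcripts were dimmer after UVB in both genotypes. Weaker hybridisation or array scaling is argued against by the hybridisation spike-ins, whose lower median over the genotypes was 0.0078 on the log2 scale. Of the 18 spike-in probe sets 3 lie above 6400 units. The spike-ins enter at hybridisation and measure neither RNA per cell nor the amount of labelled sample RNA on an array. A smaller amount of labelled RNA from the irradiated samples was not tested and stays open. Degraded RNA in the irradiated samples cannot be told apart from a change in the cells. The 5' over 3' ratio of Actb and Gapdh changed by -0.069 at the lowest, but these probe sets read 9209 to 13552 units, where a ceiling of the scanner range cannot be excluded. Blocked elongation along long genes predicts a larger fall for longer genes, and the Spearman correlation of span and response was -0.31 in the genotype with the weaker trend, so UVB damage may contribute, while a difference in mRNA stability between short and long genes stays open.

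Cornified envelope and alarmin transcripts were lower in the KO-labelled arrays, a pattern picked from the 36 lists after their medians were seen. A lower share of keratinocytes as the whole cause is argued against by the basal keratinocyte list, whose lower median over the conditions was -0.0071 relative to matched lists. Before matching, its 15 members had a median of 0.13 (SD 0.21) unirradiated and 0.07 (SD 0.35) irradiated, against -0.50 and -1.04 for late differentiation genes. Fibroblast markers lay at 0.71 and 0.62 relative to matched lists (both percentile 100), melanocyte markers at 0.38 (percentile 99.99) and 0.21 (percentile 95.94), and suprabasal genes at -0.16 (percentile 1.06) in irradiated cells, though inside the bounds at -0.11 (percentile 5.18) with quantile normalization. In unirradiated cells endothelial markers lay at -0.53 and leukocyte markers at -0.43, the latter inside the bounds at -0.24 (percentile 3.0) with centring. These lists have only 4 and 6 measured members, with 0 past 2-fold in either. In irradiated cells they lay at -0.09 (percentile 25.32) and -0.18 (percentile 4.46). A larger share of fibroblasts or melanocytes as a part of the difference stays open. Array scaling that varies with signal is argued against because the highest percentile of either list under quantile normalization was 0, while 1 factor for a whole array largely cancels against matched lists and was not tested by centring. A difference in culture maturation unrelated to genotype cannot be told apart from the genotype, because there is 1 array per group. An effect of p38alpha loss stays open with it, untested.

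The UVB response of MAPK phosphatase and chemokine transcripts was smaller in the KO-labelled pair, also picked after the medians were seen. Array scaling that varies with signal is argued against, since the highest median difference of responses of either list under quantile normalization was -0.40 relative to matched lists. Cultures in different states before irradiation cannot be told apart from a genotype effect, since the MAPK phosphatase list already lay at -0.20 (percentile 1.29) before irradiation and -0.60 after, and each group has 1 array. Chemokines lay at -0.06 before (percentile 25.78) and -0.44 after (percentile 0.01). An effect of p38alpha loss stays open with them, untested.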

How the results depend on the processing

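The matching of random lists on gene span was the only test here chosen after the result was seen. For the results that follow the cause was not tested, except that lower or higher thresholds and floors admit more or fewer genes by construction. Counts are given as genes higher and lower (for the difference of responses, larger and smaller in KO-labelled cells) in the order UVB in WT, UVB in KO-labelled cells, KO-labelled against WT unirradiated, the same irradiated, and the difference of responses. As deposited they were 68 and 3962, 21 and 4492, 203 and 87, 163 and 169, 159 and 355. Quantile normalization gave 622 and 1086, 484 and 934, 60 and 83, 259 and 321, 291 and 319. Median centring gave 1309 and 843, 1022 and 740, 59 and 76, 213 and 365, 237 and 353. A floor at the 25th percentile gave 293 and 5167, 200 and 6147, 1038 and 523, 654 and 660, 884 and 1626, and one at the 75th gave 38 and 1855, 6 and 2201, 33 and 23, 22 and 73, 7 and 56. At least 3-fold left 22 and 1695, 4 and 1839, 13 and 15, 14 and 46, 15 and 51. At least 1.5-fold gave 163 and 6609, 88 and 7631, 1177 and 383, 935 and 608, 676 and 1493. The mean over probe sets and leaving out cross-hybridising probe sets kept all 14 counts within 1.5 times.

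In limma, 80 genes rose and 7899 fell after UVB as deposited, 2314 and 2302 with quantile normalization, 4184 and 1702 with centring, and 40 and 6746 with only the tested factor. For genotype, 110 were higher and 73 lower as deposited, 96 and 157 with quantile normalization, 65 and 142 with centring, 267 and 141 with the floor at the 25th percentile, and 207 and 98 at the 75th. Without the intensity trend 0 and 0 passed (1170 and 355 at an unadjusted p under 0.05), and with only the tested factor 0 and 0 (17 and 31). The correlation of UVB responses was 0.61 with the floor at the 25th percentile and within 0.1 of 0.81 under the other alternatives, and that of genotype differences was 0.15 and 0.49 with the floor at the 25th and 75th percentile against 0.35.

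Some list medians reversed. Relative to matched lists, the difference of responses was 0.099 for immediate early genes with the floor at the 25th percentile and 0.033 for the prostaglandin pathway with the floor at the 75th. Ribosomal proteins moved to -0.018 for UVB in KO-labelled cells, 0.013 for KO-labelled against WT unirradiated and -0.030 for the difference of responses under quantile normalization. Under centring the UVB response in KO-labelled cells became 0.14 for Hspa8, 0.095 for Itga6, 0.084 for Lgr5, 0.097 for Oasl1, 0.15 for Rpa2, 0.52 for Sesn2 and 0.027 for Tslp, and under quantile normalization 0.031 for Lgr5 and 0.43 for Sesn2. In WT it became 0.36 for Hspa8 and 0.048 for Col5a1 under centring, and 0.37 for Arntl without cross-hybridising probe sets. Another probe set was the brightest for Hspa8, Rpa2 and Sesn2 under centring and for Sesn2 under quantile normalization. Of the single-gene log2 differences compared, 505 were classed as the same under centring, 90 as weaker and 19 as stronger. Under quantile normalization these were 524, 82 and 15. With the floor at the 75th percentile 470 were the same and 153 weaker. Of the list medians, 160 kept their direction and side of the percentile bounds under quantile normalization, 167 under centring, 161 and 135 under the lower and higher floor, 159 with the mean over probe sets and 148 without cross-hybridising probe sets. With lists matched on signal and gene span, 90 did, 12 left the outer percentiles, among them lipid barrier genes in both genotypes (2.70 and 3.18) and EGFR genes in WT (3.04), and 3 entered them. The additive limma model compared irradiated with unirradiated arrays within each genotype. Pairing by culture or animal was not possible because each group has 1 array and the labels give no numbers that pair them. Leaving out an array leaves 0 residual degrees of freedom and was not a test. Signal over the floor limits weak genes, since 43.1% and 43.6% of probe sets reached it on the irradiated arrays.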

Other observations

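The test of lists matched on gene span was chosen only after the result was seen. As deposited, most cell cycle genes were lower after UVB in both genotypes, and the counts of members rising and falling depend on the scaling. Of 22 S phase genes, 21 fell in limma, with Ccne2, the cyclin E2 gene, 5.46-fold lower in WT and 6.16-fold lower in KO-labelled cells and the replication licensing gene Cdc6 5.19-fold and 4.53-fold lower. Of 27 G2 and M phase genes, 25 fell, with Ccnf 10.2-fold and 11.4-fold and the spindle kinase gene Aurka 4.30-fold and 3.87-fold lower. Adjusted over the list alone the counts were also 21 and 25, while median centring gave 6 rising and 4 falling S phase genes and 10 and 6 for G2 and M phase. Relative to matched lists these lay at -0.25 and -0.28 for S phase (percentiles 5.31 and 2.64) and -0.10 and -0.32 for G2 and M phase (percentiles 26.45 and 1.98). The S phase list lay below the bounds in both genotypes with quantile normalization (percentiles 2.09 and 0.93) and against lists matched also on span, at -0.32 and -0.34 (percentiles 1.46 and 0.90), and with centring in KO-labelled cells only (percentiles 3.0 and 1.92). Of 23 nucleotide excision repair genes 19 fell (percentiles 80.83 and 84.36), while 6 rose and 2 fell with quantile normalization and 13 and 2 with centring, with the nuclease gene Ercc4 at least 6.21-fold lower in WT. Of 33 p53 targets 20 fell and 3 rose (percentiles 86.57 and 56.22), with Gadd45a rising, while 12 rose and 6 fell with quantile normalization and 17 and 3 with centring. Of 22 apoptosis regulators 18 fell (percentiles 17.14 and 6.27), with Apaf1, which activates caspases, 10.8-fold and 7.50-fold lower, and 3 rose and 7 fell with quantile normalization (KO-labelled percentile 0.34) and 7 and 6 with centring. Of 12 circadian clock genes 11 fell (percentiles 8.78 and 23.23), with Clock 8.38-fold and 5.33-fold lower, and 0 rose and 5 fell under either other scaling. Of 17 p38 pathway genes 16 fell (percentiles 11.62 and 2.30, the latter 2.59 with quantile normalization and 2.92 with span matching), while 1 of 18 rose and 6 fell with quantile normalization and 4 and 4 with centring, with Atf2 6.90-fold and 5.61-fold lower. Of 15 basal keratinocyte genes 11 fell (percentiles 24.89 and 12.80), with the epidermal regulator gene Trp63 11.1-fold and 8.2-fold lower, while 2 rose and 5 fell with quantile normalization and 10 and 2 with centring.

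Several groups stood near or above matched lists after UVB. Histone transcripts, with 6 measured, lay 0.49 and 0.64 above in WT and KO-labelled cells (percentiles 99.5 and 99.95), and 2 rose, H3f3b and H1f2, and 2 fell, against 4 and 1 with quantile normalization and 6 and 0 with centring. In WT the histone list lay inside the bounds with centring, at 0.35 (percentile 94.38), and with span matching, at 0.33 (percentile 96.12). Ribosomal protein genes lay 0.14 and 0.24 above (percentiles 99.68 and 99.99), and 0 of 20 rose or fell in limma, while all 20 rose after median centring. With quantile normalization the ribosomal list lay inside the bounds, at 0.024 and -0.018 (percentiles 68.95 and 38.99), and with span matching the WT list did (percentile 96.45). A ceiling of the scanner range cannot be excluded for such bright probe sets. Interferon-stimulated genes lay 0.23 and 0.50 above (percentiles 88.6 and 99.55), with 1 of 15 rising, Irf7, and 4 falling, against 0 and 3 adjusted over the list alone and 5 and 1 with centring. Of 13 heat shock genes 1 rose and 7 fell (percentiles 63.57 and 72.8), of 16 NRF2 genes 10 fell (percentiles 94.37 and 97.21), and of 21 unfolded protein response genes 2 rose and 13 fell (percentiles 90.02 and 94.76). Of 15 NF-kB feedback genes 9 fell (percentiles 50.76 and 44.04), of 11 AU-rich-element and decay factors 2 rose and 9 fell (percentiles 73.91 and 28.12), of 9 prostaglandin genes 7 fell (percentiles 40.08 and 32.38), and of 11 MAPK phosphatases 2 rose and 7 fell (percentiles 99.25 and 21.21). Of 19 suprabasal genes 10 fell (percentiles 91.34 and 53.48), of 17 alarmin genes 6, or 3 adjusted over the list alone (percentiles 99.36 and 80.86, the former 96.3 with span matching), and of 10 reference genes 5 (percentiles 80.92 and 89.74, the latter 98.74 with span matching), with Tbp 5.03-fold and 6.33-fold lower. With centring the counts were 12 rising and 0 falling heat shock genes, 9 and 2 for NRF2, 16 and 1 for the unfolded protein response, 6 and 0 for NF-kB feedback, 6 and 3 for decay factors, 4 and 2 for prostaglandins, 13 and 3 for suprabasal genes, 13 and 0 for alarmins and 9 and 1 for reference genes, and 4 and 4 for MAPK phosphatases. With quantile normalization they were, in the same order, 3 and 3, 7 and 2, 7 and 1, 5 and 2, 2 and 3, 3 and 2, 6 and 3, 4 and 1, 3 and 2, and 2 and 4. Among other cell types, 12 of 19 fibroblast, 9 of 13 melanocyte, 1 of 6 leukocyte, 2 of 4 endothelial, 0 of 6 muscle and 5 of 7 Merkel, sweat or hair follicle markers fell and 0 rose, and 0 erythroid markers were measured. Their percentiles in WT and KO-labelled cells were 97.7 and 95.0 for fibroblast, 97.74 and 78.97 for melanocyte, 58.84 and 99.52 for leukocyte, 62.69 and 94.63 for endothelial, 95.14 and 98.53 for muscle and 75.11 and 83.86 for Merkel, sweat or hair follicle markers. Against lists matched also on span, fibroblast and melanocyte markers in WT lay at percentiles 99.17 and 99.14 and muscle markers in KO-labelled cells at 95.03. With centring 13 of 19 fibroblast markers rose and 1 fell, 5 of 13 melanocyte markers rose and 1 fell, and 0 markers of the other types fell. With quantile normalization 8 of 19 fibroblast markers rose and 1 fell, and 1 of 13 melanocyte markers rose and 1 fell.

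Genes with a longer genomic span had a larger fall after UVB. In WT the shortest of 5 equal groups of genes by span, with a median span of 4.19 kb, had a median log2 difference of -0.36 and the longest, at 113.3 kb, one of -0.96. The Spearman correlation across 11366 genes, which are not independent replicates, was -0.33 in WT and -0.31 in KO-labelled cells. Among genes of low, middle and high mean signal it was -0.20, -0.30 and -0.46 in WT and -0.18, -0.28 and -0.43 in KO-labelled cells, and with quantile normalization -0.28 and -0.25 over all genes. The correlation of span with the difference of responses was 0.06.

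Late differentiation genes, chemokines and immediate early genes are short, with median spans of 1.75, 2.40 and 5.34 kb against 33.0 kb for Notch and Wnt genes. Against lists matched on signal and span, the WT responses lay at 0.42 for late differentiation (percentile 99.99), 0.55 for chemokines (percentile 99.95), 0.66 for immediate early genes (percentile 100) and -0.60 for Notch and Wnt genes (percentile 0.24). In KO-labelled cells late differentiation lay at 0.25 (percentile 96.42) and immediate early genes at 0.12 (percentile 83.3), and MAPK phosphatases in WT at 0.31 (percentile 92.88). The differences of responses lay at -0.65 for MAPK phosphatases and -0.54 for late differentiation, both at percentile 0, and at -0.53 for chemokines (percentile 0.05).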
